A study of Mus musculus with 6 samples.

How the data were processed

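RNA from BV2 cells, an immortalised mouse microglial line, was hybridised to 6 Affymetrix whole-transcript mouse arrays, 1 per sample. Per the labels' protocols, all 6 samples received telmisartan for 2 h and then lipopolysaccharide (LPS) for 1 h, 3 h in all, and 300 ng of total RNA per sample was labelled after DNase treatment. The sample labels put 3 samples in the group with telmisartan and LPS and 3 in the group that also received GW9662. The labels give no drug doses. They describe the samples of a group as independent, without saying whether they came from separate cultures. The p-values of single genes therefore measure the spread between these samples, which may in part be technical. The file headers and the array names give a second-generation mouse gene array, while the labelling protocol names its predecessor, and the values were treated as those of the former.

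The values analysed are deposited log2 expression values made by the authors with robust multi-array averaging (RMA) in Affymetrix Expression Console, per the submitters' processing notes. Per the file headers, the engine was Affymetrix Power Tools 1.4.1.46, and background correction, quantile normalization over the 6 arrays together and median polish of the probes gave 1 log2 value per probe set and array. Quantile normalization gives every array nearly the same distribution, so a shift of most transcripts in 1 direction would not be visible in these values. A deposited log2 table of the authors with 41345 probe sets and 5 decimals was the source of all results, and a second deposited table of the same values with 2 decimals, which differed from it by at most 0.005, was an alternative. Versions of Expression Console and of the array annotation are not given in the sources used here.

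Probe sets were named through a table that pairs them with the platform annotation. Of the 41345 probe sets, 23521 carried 1 gene symbol, 1820 carried several and 16004 had no annotation in that table. Of the probe sets with 1 symbol, 23328 had that symbol in a table of mouse RefSeq genes. No genome coordinates are given, since no build is named for this annotation. Each of the 22180 genes was represented by its brightest probe set, and genes with a mean log2 level over the 6 arrays of at least 6.15, the median over all probe sets, were tested, which left 12212. Probe sets with several symbols or none were kept out of the main test. All 6 arrays had a sample in the labels, and no column was left out.

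The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are given as the log2 value with GW9662 minus the log2 value without it, with the standard error (SE) of the moderated fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists with at least 5 tested members. The 27 fixed lists covered the NF-kB and TLR4 response, immediate early genes, type I interferon, targets of PPARG, NRF2, the aryl hydrocarbon receptor and LXR, heat shock, the ATF4 and unfolded protein responses, cholesterol synthesis, hypoxia, the cell cycle in 2 parts, respiratory chain, mitochondrial genome, ribosome, microglia and alternative activation markers, drug targets, housekeeping genes, and markers of astrocytes, neurons, oligodendrocytes, fibroblasts and lymphocytes. A further list, tested and counted among them, is not reported here. The neuron and lymphocyte lists had 3 tested members each and were not tested as lists. The camera test was repeated with a correlation estimated from the data. That repeat also rests on the 4 residual degrees of freedom of the arrays, so a call lost in it need not reflect the correlation alone. Limma's fry was run beside it. Its directional p asks whether the members of a list move on balance 1 way, and its mixed p asks whether they change in either direction. The number of members past the threshold is given over all genes and adjusted over the list alone.

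The groups, the test, the level filter, the lists, the rule for naming genes and all alternatives except those stated otherwise were fixed before the data were examined. The rule named up to 12 genes per direction among those past the threshold whose groups did not overlap. Where fewer than 5 passed, the direction was filled up to 8 genes by the smallest p among fully separated genes, leaving out gene models, olfactory and vomeronasal receptors and small RNAs. Up to 4 passing members of each list were named, or the 2 members with the smallest p where none passed. Pparg, Agtr1a, Agtr1b, Tlr4, Tnf, Il1b, Il6, Ptgs2, Cd36 and Hmox1 were named in any case. Members of called lists that passed only when adjusted over the list alone, and histone genes named as a set, were named after their values were seen.

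The scripts were tested on simulated data for the comparison of 3 and 3 arrays over 12212 genes. With 200 changed genes, the 3 sizes mixed in each draw, 65.4% were recovered at a log2 change of 0.5, 94.9% at 1 and 100% at 2. Of the calls, 4.25% were false. Many large changes in a draw ease the adjusted threshold for small ones. Recovery with as few changed genes as were called here was not tested and may be lower. A shift of -0.15 in 1 list was recovered in 20 of 20 draws, with 0 false calls in 480 tests of unchanged lists. Simulated genes were independent of each other, which real genes are not. The number of arrays limits the precision: at the median within-group SD of 0.101, an unadjusted p of 0.05 needed a log2 difference of 0.187. Alternatives were the second table, no level filter and a level of at least 7, the mean over all probe sets of a gene, median centring, repeated quantile normalization, trended and robust variance models, array weights, a replicate block, no moderation of the spread, each array left out in turn and an estimated correlation for the lists. Leaving out both arrays that stood apart was added after the data were seen.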

Results

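Gene expression was measured on 6 arrays in BV2 mouse microglial cells given telmisartan and then LPS, 3 without and 3 with GW9662. Telmisartan is a blocker of the angiotensin II type 1 receptor and a partial agonist of the nuclear receptor PPARG, GW9662 is an irreversible PPARG antagonist, and LPS is a bacterial cell wall component that activates TLR4. The comparison asks which transcripts of cells treated with telmisartan and LPS differ when the antagonist is added. Arrays without telmisartan or without LPS were not analysed here, so no value below measures the effect of either. The 6 arrays correlated with each other at 0.990 to 0.996 over the genes tested. Replicate 3 of telmisartan and LPS and replicate 2 of the group with GW9662 lay apart from the other 4 on the first principal component, which held 42.8% of the variance, with scores of 14.6 and 7.55 against -8.15 to -0.98.

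With GW9662, 3 genes rose and 2 fell among 12212 tested. Slc7a11, the cystine importer that feeds glutathione synthesis, rose 2.22-fold, Plin2, a coat protein of lipid droplets, rose 1.67-fold, and Srxn1, which repairs oxidised peroxiredoxins, rose 1.47-fold. The histone genes H4c1 and H1f3 were 1.84-fold and 1.86-fold lower. As a group, target genes of NRF2, the transcription factor of the response to electrophiles and oxidants, rose, and so did ATF4 target genes, while genes of the primary response to TLR4 and interferon-response genes fell. The NRF2 list kept its call when the correlation between genes was estimated (adjusted p = 0.0142), and the ATF4, TLR4 and interferon lists did not (adjusted p = 0.136, 0.249 and 0.542 with an estimated correlation). The estimate for the NRF2 list was 9.03e-05, below the preset 0.01, and those for the ATF4, TLR4 and interferon lists were 0.105, 0.117 and 0.344. The unadjusted camera p of the NRF2 list still rose from 1.28e-18 to 0.00057, so the repeat changed more than the correlation.

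Slc7a11 (probe set 17405082) went from 9.71 ± 0.19 to 10.86 ± 0.22 (log2 level, SD, n = 3 in each group), a difference of 1.15 ± 0.13 (SE). Plin2 (probe set 17426981) went from 9.88 ± 0.13 to 10.62 ± 0.08, a difference of 0.74 ± 0.08, and Srxn1 (probe set 17377666) from 8.98 ± 0.03 to 9.54 ± 0.04, a difference of 0.56 ± 0.06. All 3 had an adjusted p of 0.0453 in limma. H4c1 (probe set 17291229) went from 7.21 ± 0.04 to 6.33 ± 0.03, a difference of -0.88 ± 0.06 at an adjusted p of 0.00449, and H1f3 (probe set 17285829) from 9.73 ± 0.01 to 8.83 ± 0.16, a difference of -0.90 ± 0.09 at an adjusted p of 0.0341. In all 5 genes the 3 arrays of one group lay wholly above those of the other. That held for 9.37% of all genes tested, where chance gives 10%, and 99.8% of the genes differed by less than 0.5 on the log2 scale. A second, dim probe set of Slc7a11 at a mean log2 level of 4.11 differed by 0.35, and the mean of both probe sets gave 0.75 for Slc7a11 at an adjusted p of 0.0680.

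**Figure D1:**
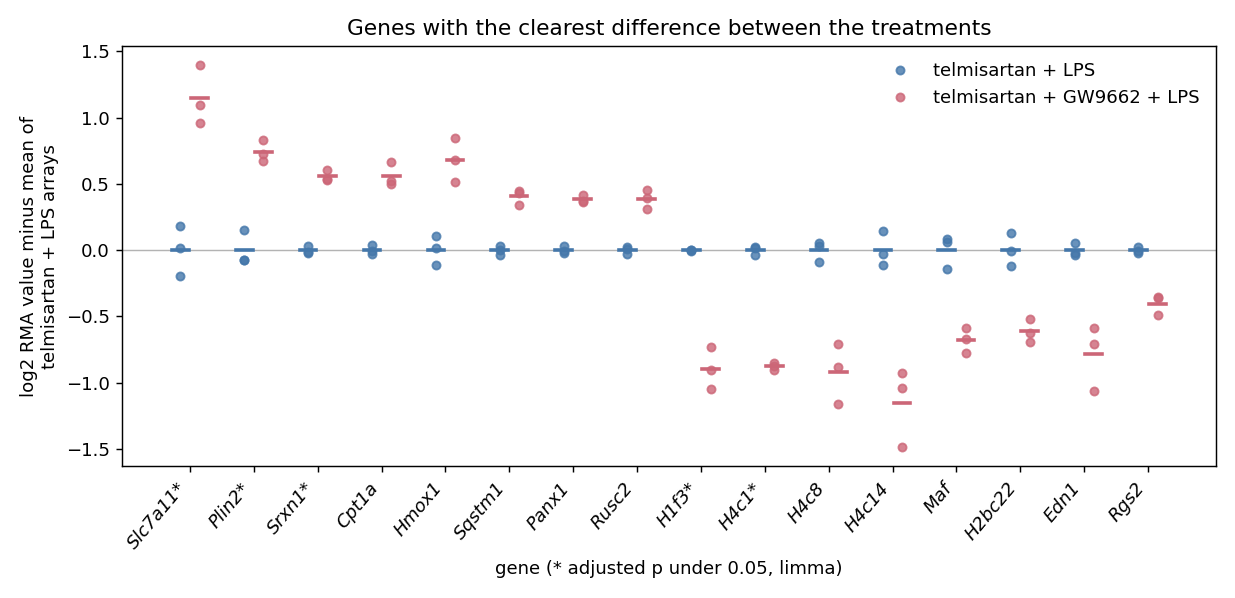
Log2 RMA value of 16 genes on each array, minus the gene's mean over the telmisartan and LPS arrays (vertical axis, log2 units), with 3 points per group and a line at the group mean. Asterisks mark the 5 genes with an adjusted p under 0.05, and in every gene shown the groups do not overlap, which was a condition for being shown.

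Next in rank were genes that did not pass. Cpt1a, which carries fatty acids into mitochondria, differed by 0.56 ± 0.07, the histone genes H4c8 and H4c14 by -0.92 ± 0.11 and -1.15 ± 0.14, and the transcription factor gene Maf by -0.68 ± 0.09, all at an adjusted p of 0.0531. Hmox1, which encodes the inducible haem oxygenase, differed by 0.68 ± 0.10 (adjusted p = 0.113) and the autophagy receptor gene Sqstm1 by 0.41 ± 0.06 (adjusted p = 0.142). Panx1 and Rusc2 each differed by 0.38. On the lower side, the histone gene H2bc22 differed by -0.61 ± 0.08 (adjusted p = 0.0832), Edn1, the gene of the vasoconstrictor endothelin-1, by -0.79 ± 0.12 (adjusted p = 0.123), and Rgs2, a brake on G protein signalling, by -0.40 ± 0.07 (adjusted p = 0.192). The dimmer probe sets of Maf and Rgs2 differed by -0.21 and -0.02. Probe sets of histone genes can match transcripts of near-identical copies, so which copy differed is uncertain. Gathered by symbol after the data were seen, probe sets of the H4 class had a median difference of -0.75 (13 of 13 negative), those of H3 -0.52 (9 of 9), H2B -0.30 (11 of 12), H1 -0.11 (3 of 3) and H2A -0.05 (10 of 13).

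**Figure D2:**
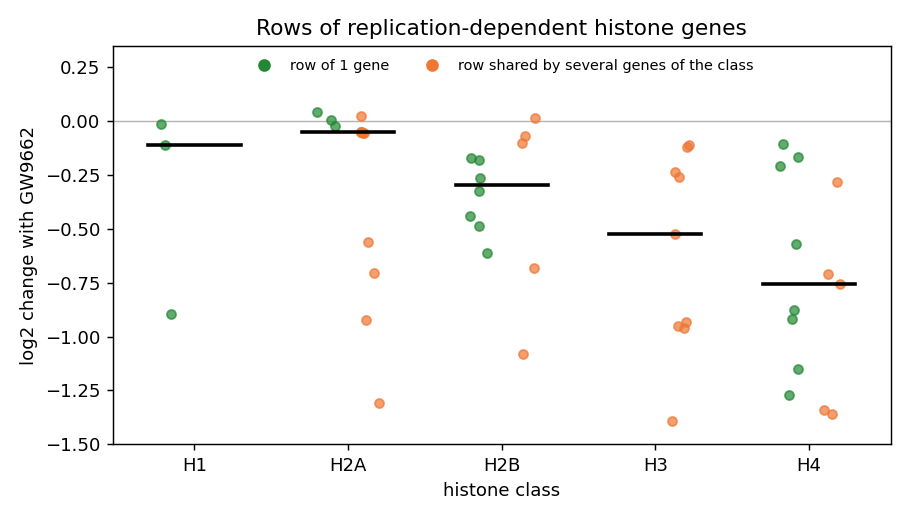
Log2 difference (vertical axis, value with GW9662 minus value without) of each probe set of replication-dependent histone genes by histone class (horizontal axis), green for probe sets of 1 gene and orange for those shared by several genes of the class, with a line at the class median. The medians run from -0.05 for H2A to -0.75 for H4, and this set was gathered after the data were seen.

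The number of genes past the threshold moved with the fit and with single arrays. It was 4 higher and 6 lower with median centring or repeated quantile normalization, and 27 higher and 22 lower with array weights. No gene passed with no moderation of the spread or with the replicate number as a block. These 2 fits gave 610 and 379 genes at an unadjusted p under 0.05, against 543 in the main test. None of these counts exceeds the share of 0.05 of 12212 genes that chance alone gives on average. Of the 5 calls, 2 were kept without replicate 2 of the group with GW9662, 1 without replicate 2 and 1 without replicate 3 of telmisartan and LPS, 0 without any one of the other 3 arrays and 0 without both arrays that stood apart (944 genes at an unadjusted p under 0.05). In these fits on fewer arrays the differences were 1.03 to 1.27 for Slc7a11, 0.70 to 0.82 for Plin2, 0.54 to 0.58 for Srxn1, -0.90 to -0.86 for H4c1 and -0.98 to -0.82 for H1f3.

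NRF2 target genes rose with GW9662. Of 29 tested, 23 had a positive difference, with a mean of 0.20 and a median of 0.14 on the log2 scale (camera adjusted p = 3.19e-17), and the call held with an estimated correlation (adjusted p = 0.0142) and in fry (adjusted p = 0.00542). The correlation estimated for this list was 9.03e-05, below the preset 0.01, so the repeat did not test the list against a higher correlation. Slc7a11 and Srxn1 passed over all genes, and 10 members passed when adjusted over the list alone. These included, beside Hmox1 and Sqstm1, the glutathione synthesis genes Gclm at 0.42 ± 0.07 and Gclc at 0.28 ± 0.07, the thioredoxin reductase gene Txnrd1 at 0.26 ± 0.07, Osgin1 at 0.31 ± 0.07, Slc48a1 at 0.32 ± 0.09 and Trib3 at 0.47 ± 0.09. The transcript of NRF2 itself, Nfe2l2, differed by -0.01 ± 0.06 (-0.02 to 0.01 with 1 array left out). The level of the list on each array, relative to its mean over the 6 arrays, was 0.08 to 0.14 with GW9662 and -0.11 to -0.10 without. This separation gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow.

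ATF4 targets, which serve amino acid supply and the integrated stress response, rose as a list, with 28 of 30 positive and a mean difference of 0.15 (camera adjusted p = 2.53e-14). The call was lost with an estimated correlation (adjusted p = 0.136 with an estimated correlation), and fry gave an adjusted p of 0.0477. Slc7a11 passed over all genes, and 4 members passed when adjusted over the list alone, namely Slc7a11, the glutathione-degrading enzyme gene Chac1 at 0.37 ± 0.06, Trib3, and the mitochondrial enzyme gene Pck2 at 0.22 ± 0.06. Slc7a11 and Trib3 are on the NRF2 list too. Atf4 itself differed by 0.07 ± 0.06, and the amino acid synthesis genes Asns and Psat1 by 0.07 ± 0.07 and 0.04 ± 0.07. With 1 array left out, Asns ranged from 0.04 to 0.11 and Psat1 from 0.0099 to 0.09.

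Genes of the NF-kB and TLR4 primary response fell as a list. Of 53 tested, 44 had a negative difference, with a mean of -0.15 and a median of -0.13 (camera adjusted p = 8.34e-10), and the call was lost with an estimated correlation (adjusted p = 0.249 with an estimated correlation), while fry gave an adjusted p of 0.122. No member passed over all genes, and 6 passed when adjusted over the list alone. They were the chemokine genes Ccl7 at -0.93 ± 0.16, Ccl2 at -0.58 ± 0.13 and Ccl4 at -0.38 ± 0.09, the phosphodiesterase gene Pde4b at -0.33 ± 0.07, and Socs3 at -0.40 ± 0.07 and Tnfaip3 at -0.32 ± 0.08, which encode inhibitors of cytokine and NF-kB signalling. Among the classical cytokine genes of this response, Il1b differed by -0.61 ± 0.20, Il6 by -0.45 ± 0.20, Tnf by -0.24 ± 0.07 and the cyclooxygenase gene Ptgs2 by -0.15 ± 0.07, none past the threshold over all genes (adjusted p from 0.947 to 0.994). Without replicate 1 of the group with GW9662, Il1b differed by -0.37 and Il6 by -0.25, and without its replicate 2 Il6 differed by -0.69. A dimmer probe set of Socs3 differed by -0.06, and the mean of both gave -0.23. Ccl3 and Nos2 differed by less than 0.01 in size, and with 1 array left out Ccl3 ranged from -0.02 to 0.0095 and Nos2 from -0.05 to 0.05. Fully separated groups were seen downward in 14 members and upward in 2, Tnfaip2 at 0.21 ± 0.07 and Plaur at 0.13 ± 0.07. Neither of these 2 passed, even adjusted over the list alone. All 3 arrays with GW9662 had a lower list mean (-0.15 to -0.01) than the 3 without (0.06 to 0.09).

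Interferon-response genes also fell as a list, with 23 of 26 negative and a mean of -0.17 (camera adjusted p = 9.16e-07; adjusted p = 0.542 with an estimated correlation), and fry gave an adjusted p of 0.357. Over all genes 0 members passed, and 4 passed when adjusted over the list alone: the chemokine genes Cxcl10 at -0.60 ± 0.12 and Ccl5 at -0.34 ± 0.09, and the antiviral genes Rsad2 at -0.44 ± 0.10 and Oasl2 at -0.36 ± 0.10. The list means of the groups overlapped on 1 array, since replicate 1 of telmisartan and LPS lay at -0.03 and the arrays with GW9662 at -0.19 to -0.01. With array weights, of which the highest, 5.74, was that of this replicate, the list's adjusted p was 0.0677.

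**Figure D3:**
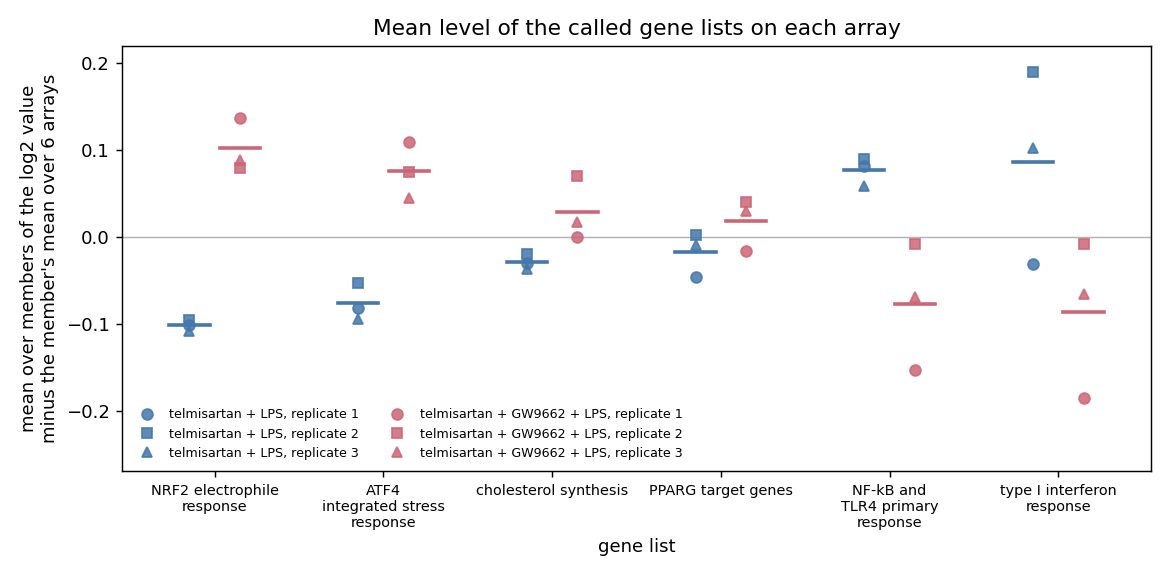
Mean level of the 6 called gene lists on each array (vertical axis, mean over members of the log2 value minus the member's mean over the 6 arrays), coloured by group, with marker shapes for replicate numbers and a line at each group mean. The NRF2 list lies at 0.08 to 0.14 on the arrays with GW9662 and at -0.11 to -0.10 on those without.

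PPARG target genes had differences of both signs, and those that passed were higher. Plin2 passed over all genes and Cpt1a when adjusted over the list alone, both higher with the antagonist. The members named next did not pass, even adjusted over the list alone. Hilpda, another lipid droplet gene, differed by 0.23 ± 0.08. The classical target Fabp4, a fatty acid carrier, differed by -0.26 ± 0.09, Aqp7, a glycerol channel, by -0.21 ± 0.07, the cholesterol exporter gene Abca1 by -0.24 ± 0.09, and Cd36, a fatty acid uptake receptor, by -0.03 ± 0.13. Of 31 tested, 17 were positive. The list was called higher by a narrow margin, with a mean of 0.04 and a median of 0.01 (camera adjusted p = 0.0499), and the call was lost with an estimated correlation (adjusted p = 0.458 with an estimated correlation). It was also lost without replicate 1 (adjusted p = 0.238) or replicate 3 (adjusted p = 0.220) of telmisartan and LPS, without replicate 2 (adjusted p = 0.154) or replicate 3 (adjusted p = 0.118) of the group with GW9662, and with either rescaling (adjusted p = 0.101 and 0.0583). Fry gave an adjusted p of 0.233 for a shift in 1 direction and 0.00075 for change in either direction. Pparg itself lay at a log2 level of 5.44 ± 0.12 with GW9662 and 5.49 ± 0.13 without, below the level filter of 6.15, as did the angiotensin receptor genes Agtr1a (5.40 and 5.46) and Agtr1b (5.92 and 6.10). Ppard, the gene of a related receptor, differed by 0.22 ± 0.09 and Tlr4 by -0.12 ± 0.09, and neither passed. With 1 array left out, Cd36 ranged from -0.17 to 0.07 and Tlr4 from -0.18 to -0.01, the latter without replicate 3 of telmisartan and LPS.

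Cholesterol synthesis genes rose as a list by a small amount, with 16 of 22 positive and a mean of 0.06 (camera adjusted p = 0.000532; adjusted p = 0.232 with an estimated correlation), and fry gave an adjusted p of 0.233. No member passed, either over all genes or adjusted over the list alone. The members with the smallest p were the sterol pathway genes Mvd at 0.19 ± 0.08 and Lss at 0.19 ± 0.08. Without replicate 2 of the group with GW9662, which stood apart on the first principal component, the adjusted p of the cholesterol list was 0.0624, and the mean was 0.04.

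**Figure D4:**
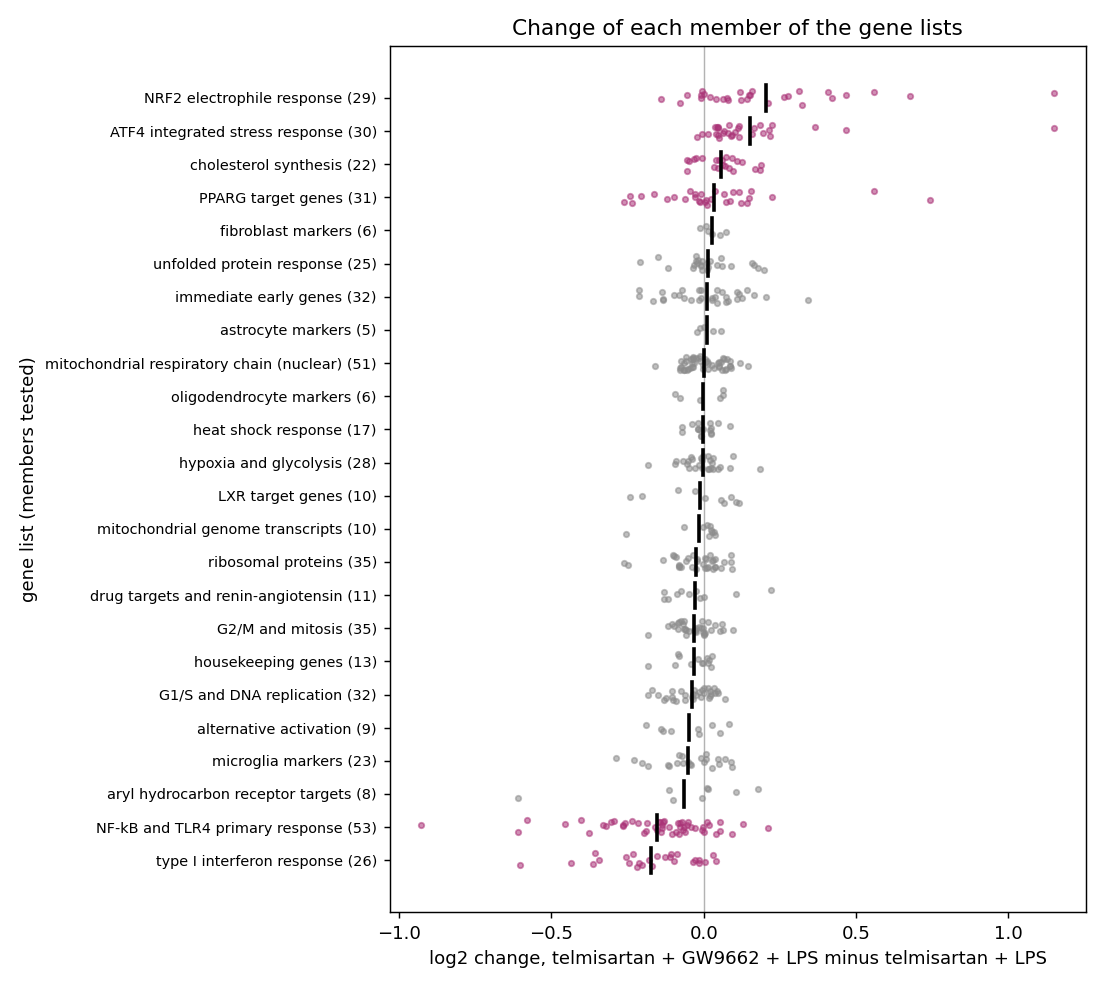
Log2 difference (horizontal axis, value with GW9662 minus value without) of each tested member of the gene lists reported (vertical axis, number of members in parentheses), with a black line at the list mean. Lists called by camera are purple, and their means run from 0.20 for the NRF2 list to -0.17 for the interferon list.

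The other 19 lists were not called, and except for Plk3 none of their members passed, even when adjusted over the list alone. Among stress lists, camera's adjusted p was 0.691 for heat shock (17 genes; Cacybp -0.07, Chordc1 0.09), 0.378 for the unfolded protein response (25 genes; Ern1 0.20, Herpud1 0.18) and 0.676 for hypoxia and glycolysis (28 genes; Vegfa 0.18, Egln3 -0.18). Aryl hydrocarbon receptor targets (8 genes, adjusted p = 0.972) included Xdh at 0.18 and, from the inflammatory side, Il1b, and LXR targets (10 genes, adjusted p = 0.740) included Mylip at -0.20. Replication genes (32 genes; Ccne1 -0.15, Cdc6 -0.17) and mitotic genes (35 genes; Cdk1 -0.18, Ccnb2 -0.12) had adjusted p of 0.400 and 0.606. Microglia markers (23 genes; Aif1 -0.20, C1qb -0.29) and alternative activation genes (9 genes; Msr1 -0.19, Igf1 -0.11) had adjusted p of 0.400 and 0.676. Drug target genes (11 genes; Ppargc1b -0.13) had an adjusted p of 0.915. Without replicate 2 of telmisartan and LPS, C1qb differed by -0.15 and Igf1 by -0.06, and without its replicate 3, Msr1 differed by -0.08 and Cacybp by -0.04. Ccnb2 differed by -0.06 without replicate 1 of the group with GW9662, and Chordc1 ranged from -0.0043 to 0.17 with 1 array left out.

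Signs of RNA quality and markers of other cells gave no called list. Camera's adjusted p was 0.972 for ribosomal proteins (35 genes; Rpl5 -0.25, Rplp2 -0.26), 0.905 for transcripts of the mitochondrial genome (10 genes; ND6 -0.25, ND3 -0.07) and 0.381 for the nuclear-encoded respiratory chain (51 genes; Ndufs3 0.15, Ndufb10 0.12). Housekeeping genes (13 genes; Hprt -0.18, Tbp -0.08) had an adjusted p of 0.691 and a mean of -0.03, beside a median of -0.02 over all genes tested, and their list mean was lower on all 3 arrays with GW9662. Astrocyte (5 genes; Aldh1l1 0.06, Aldoc 0.03), oligodendrocyte (6 genes; Mbp -0.10, Cnp 0.06) and fibroblast markers (6 genes; Col3a1 0.07, Acta2 0.05) had adjusted p of 0.684, 0.879 and 0.547. Of the 3 neuron and 3 lymphocyte markers, Syn1 differed by -0.12, Rbfox3 by -0.09, Ighm by -0.34 and Nkg7 by -0.12, and none passed. Without replicate 1 of the group with GW9662, Rplp2 differed by -0.07 and ND6 by -0.16, without its replicate 2, Rpl5 differed by -0.38 and Ighm by -0.15, and without its replicate 3, Ighm differed by -0.53 and Tbp and Mbp by -0.05 each. Without replicate 2 of telmisartan and LPS, Ndufb10 differed by 0.19 and Nkg7 by -0.08, and without its replicate 3, Ndufb10 differed by 0.07 and Hprt by -0.12. Among the other markers, the range with 1 array left out was -0.18 to -0.05 for Syn1, -0.25 to 0.15 for Rbfox3, 0.00098 to 0.12 for Aldh1l1, 0.0036 to 0.06 for Aldoc, 0.01 to 0.11 for Cnp, -0.04 to 0.20 for Col3a1 and -0.04 to 0.15 for Acta2. Chordc1, Aldh1l1, Aldoc, Rbfox3, Cnp, Col3a1, Acta2, Cd36 and Tlr4 took the opposite sign in at least 1 alternative, and no rescaling of the arrays was among these.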

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

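Of the tests in this part, those of replication genes, of histone classes and of the interval of the small nucleolar RNAs, and the test of the histone genes not named before, were chosen after the result was seen, and the histone set itself was formed after the data were seen.

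Histone genes lower with GW9662 stood out because probe sets kept out of the main test moved with those in it. These were 29 probe sets shared by several histone genes of 1 class, such as those matching many H3 or H4 genes at once. Their median log2 difference was -0.522, and 27 of the 29 were negative. In 18, all arrays with GW9662 lay below those without, where chance gives 10% for separation in either direction together. Several of them also match the 5 histone genes already named, so they are not independent of those. Among 7901 probe sets with several symbols or none, 0 passed in limma, with 313 at an unadjusted p under 0.05. That count is below the share of 0.05 that chance alone gives on average. Among genes with a probe set of their own, 18 of 20 replication-dependent histone genes were negative, with a mean of -0.37, or -0.41 without the arrays that stood apart. That set includes the 5 genes that prompted it. Of the other 15, 13 were negative, with a mean of -0.20 and a median of -0.17, below the central 95% of matched random lists (-0.07 to 0.02). Some of them, such as H4c9 and H4c12, are of the same class as genes that prompted the set. Their probes may match the same transcripts, so they are not independent of those either. Camera gave these 15 an unadjusted p of 4.69e-06, and p = 0.107 with an estimated correlation.

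The arguments against technical readings of the histone difference are partial. A single transcript read by probes of near-identical genes would leave at most 1 class low. Instead 3 of the 5 classes, H2B, H3 and H4, had medians (-0.30, -0.52 and -0.75) below the central 95% of random lists of the same level. Cross-reading of 1 transcript within each class stays open, since many probe sets match the same genes and the random lists treat them as independent. The H2B and H4 classes also include genes that prompted the set. Canonical histone mRNA has no poly(A) tail, so a lower yield of such RNA could contribute: the median of 74 small nucleolar RNA genes was -0.0458, just below the central range of matched lists (-0.045 to -0.00085). The 95% bootstrap interval of that median, with a lower bound of -0.0623, lay above the histone median of -0.24 and above the -0.17 of the 15 genes. That interval measures the spread between genes, not between samples. Whether small nucleolar RNA and histone mRNA would lose yield to the same degree was not tested. A lower yield as the whole cause therefore stays undecided. Fewer cells in DNA replication stay open as a biological explanation, because the replication list had a median of -0.0271, inside the range of matched lists, with members of both signs.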

How the results depend on the processing

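All alternatives were planned except leaving out both arrays that stood apart, which was chosen after the data were seen. No called value reversed among counts, lists and 82 named genes, and 11 of 1465 alternative values of the named genes changed sign, none of them called. For genes with an unadjusted p under 0.05, 950 of 950 alternative values kept their sign. That count says little, since most of these genes had fully separated groups and several alternatives leave the difference nearly unchanged. The NRF2 list was called in all 17 alternatives. For the other results that changed, the cause was not tested unless given.

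The count of 3 genes higher and 2 lower became 0 and 1 with no level filter, where more genes enter the adjustment, and 5 were lower at a level of at least 7. It was 4 and 6 with median centring or repeated quantile normalization, 6 and 7 with a variance trend, 6 and 6 with trend and robust fitting, and 27 and 22 with array weights. With no moderation it was 0 and 0, where 4 residual degrees of freedom remain. With each array left out it ranged from 0 to 0 higher and from 0 to 2 lower, and without both arrays that stood apart it was 0 and 0, where fewer samples enter.

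With the replicate number as a replicate block the count was 0 higher and 0 lower (379 genes at an unadjusted p under 0.05), and the PPARG list, at a mean of 0.0355, had an adjusted p of 0.0960, while no other list call changed. The deviations of same-numbered arrays had correlations of 0.294, -0.451 and -0.122, with both signs. So few correlations cannot decide whether equal numbers mark paired samples, and the labels do not say. The loss of all gene calls with the block is therefore not set aside.

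The 4 lists called higher became 1 with an estimated correlation, 2 without both arrays that stood apart, and 2 to 5 with each array left out. The 2 called lower became 1 with array weights and 0 with an estimated correlation. An estimated correlation leaves the means as they were but also lowers the degrees of freedom of the list test. With it, the calls of NF-kB (-0.154), interferon (-0.174), ATF4 (0.152), cholesterol synthesis (0.0578) and PPARG (0.0355) were lost. With array weights the interferon mean was -0.108 and not called (adjusted p over all alternatives 8.05e-11 to 0.542). The PPARG list was not called with the second table (0.0345), no level filter (0.0319), median centring (0.0504), quantile normalization (0.0571), array weights (0.0494) or without both arrays that stood apart (0.0282), and its mean ranged from 0.0215 to 0.0528 with each array left out (adjusted p over all alternatives 0.00969 to 0.458). Cholesterol synthesis was not called without both arrays (0.0330), with means of 0.0370 to 0.0725 with each array left out.

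These arrays give no detection calls, and the level filter at 6.15 stood in for signal over background.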

Other observations

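Leaving out both arrays that stood apart was chosen after the data were seen, and the other tests in this part were set before their results were seen.

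Immediate early genes, which cells switch on within minutes of a stimulus, had differences of both signs, 17 positive and 15 negative. Plk3, a stress-responsive kinase, differed by 0.34 ± 0.06 and passed when adjusted over the list alone, and the antiproliferative gene Btg2 differed by -0.21 ± 0.07 and did not pass. Of 32 members, 5 were fully separated upward and 2 downward, 21.9% of the list where chance gives 10%. Camera did not call a shift (adjusted p = 0.220), and fry gave an adjusted p of 0.832 for a shift in 1 direction and 0.00219 for change in either direction.

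With GW9662 the NRF2 and ATF4 lists were higher and the NF-kB and interferon lists lower, and the calls of the ATF4, NF-kB and interferon lists were lost with an estimated correlation (adjusted p = 0.136, 0.249 and 0.542). The arrays that stood apart are argued against as its source, because 4 of the 4 lists kept their direction and their call at the preset correlation without both, with means of 0.21, 0.14, -0.20 and -0.21. A level-dependent trend in intensity is argued against, because 4 of the 4 list medians lay outside the central 95% of 10000 random lists of matched level. Without the shared members Slc7a11 and Trib3, the medians of the NRF2 and ATF4 lists, 2 of 2, stayed outside that range (0.121 and 0.0865). A median moves little when 2 members are left out, so this could hardly have come out otherwise. Whether the lists share a regulator was not tested. The treatment named by the design, GW9662, stays open as a biological source, and whether it acted through PPARG or apart from it was not tested, since arrays with GW9662 and no telmisartan were not analysed here.

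The PPARG target list leaned higher with an antagonist of PPARG. Without its 3 members of smallest p the median was 0.00517, and without both arrays that stood apart it was -0.0122, both inside the range of matched random lists, as was the median of the whole list (0.00727). A median moves little when 3 of 31 members are left out, and camera compares means. The first of these tests could therefore hardly decide whether a few strong members made the lean. The list mean was 0.0355, above the median, and the highest members were Plin2 at 0.743 and Cpt1a at 0.559. Those arrays as the source of the lean cannot be told apart from no shift of the list, because members had both signs. Whether Plin2 and Cpt1a, which other PPAR receptors also regulate, responded through PPARG was not tested.

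The splits of the 6 arrays into 3 and 3, the real one included, number 10, too few for a share under 0.05. The real split gave 5 genes and the highest of the others 0, so 1 of the 10 gave as many genes. For gene lists the real split gave 6 and the highest of the others 6, so 2 of the 10 gave as many lists. Of the 9 other splits, 5 called the NRF2 list, 5 the interferon list, 3 the ATF4 list, 3 the NF-kB list, 2 cholesterol synthesis and 0 the PPARG list. These calls count either direction. Each other split sets 2 arrays of one group and 1 of the other against the rest, so part of the difference between the groups stays in it. The calls of the other splits therefore give no rate of false calls. The unadjusted camera p of the NRF2 list was 1.28e-18 in the real split and at lowest 0.00015 in the others. At an unadjusted p under 0.05, limma gave 543 genes in the real split and 148 to 2249 in the others.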
